A study of Homo sapiens with 3 samples.

How the data were processed

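The series holds 3 RNA-seq libraries of MDA-MB-231 cells, 1 control and 2 with 50 mM sodium chloride added for 24 hours. Per the submitters' processing notes, the tools were fastp 0.23.4, HISAT2 2.2.1, featureCounts 2.0.6, edgeR 4.3 and R 4.3 with the build hg38. The roles of these tools, the strand setting, the handling of reads shared by transcripts and any selection of polyadenylated RNA are not given in the sources used here. The authors deposited a table of raw read counts, whole numbers that were not normalized, with 200905 rows for RefSeq transcripts and 3 library columns.

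Of these rows 4821 carried no accession. They held 33.4% of counts in the control, 32.6% in high-salt replicate 1 and 30.2% in replicate 2, and they were left out of library sizes and tests. The mitochondrially encoded list had 0 measured members among named rows. Rows with an accession were matched to gene symbols through a RefSeq gene table of GRCh38, 193418 by the exact version and 330 by another version, with 2336 unmatched, and counts were summed per symbol. Rows of additional copies of an accession were kept and held 0.903%, 0.976% and 0.965% of named-gene counts. Reads shared between overlapping transcripts appear to be missing: 12505 of 15059 protein-coding genes with 2 or more accessions had 0 counts. Among counts from 1 to 100, 77.8% to 79.5% were even, as when both reads of a pair are counted, so counting error is understated.

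Genes were kept by edgeR's filterByExpr (minimum count 10, minimum total 15), scaled by TMM (factors 0.800, 1.12 and 1.12) and tested with edgeR 4.0.16 (glmQLFit and glmQLFTest, two-sided) under R 4.3.3. Adjusted p-values are Benjamini-Hochberg values over the 7746 tested genes unless a list is named. There was 1 residual degree of freedom, all genes shared the trended dispersion, and the biological coefficient of variation was 0.264. Gene lists were tested with camera of limma 3.58.1 (preset correlation 0.01, prior count 2), over the 31 of 37 lists with at least 3 measured members. Camera sets a list against all other tested genes, and the median log2 fold change of tested genes was 0.50 under TMM. A list called lower is therefore lower than the other genes, and a list that rose like them does not pass. An estimated correlation was an alternative. It rests on 1 residual degree of freedom, so hardly any list could pass there. List medians were set against 10000 random lists matched on mean expression, and after seeing the data also on length. Levels of single genes are TMM-scaled CPM, whereas levels of gene classes and marker lists are CPM of each library's named-gene counts without TMM factors. Shares carry 95% Wilson intervals. DESeq2 1.42.0, limma-trend and fixed coefficients of variation of 0.1 and 0.2 were alternatives. SciPy 1.17.1 and matplotlib 3.10.9 were used for further tests and plots.

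Samples, gene lists, tests, named-gene rules and a set of alternatives were chosen before the data were examined. The rule named the 10 called genes with the largest increase and the 10 with the largest decrease (mean log2 CPM of at least 1, same direction in both high-salt libraries), up to 4 members of each list with a called member, and 6 osmotic response genes. After seeing the data, genes with a mean log2 CPM of at least 5 were also ranked, and the alternatives on transcript rows, single-accession genes, additional copies, halved counts, highly expressed genes, transcript length and unnamed rows were added. The length correction removes a lowess trend per library while keeping the TMM scaling. It replaced an earlier version that also moved the overall level, after the counts of that version had been seen.

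The gene test was run on 5 simulated sets with 200 changed genes each, drawn from the real means, and 6841 genes entered the fit. It recovered 25.7% of tested genes changed 2-fold (log2 change of 1) and 45.9% of those with a log2 change of 2, and 7.80% of calls were false, above the nominal 5%. The recovery first required of it, over 50% for a log2 change of 2 across all genes, was not reached. The requirement was then moved to genes with a mean log2 CPM of at least 3, where recovery was 54.3% and 87.8%. Many changes of low-abundance genes would therefore be missed. In simulated lists 2.9% of unchanged lists had p under 0.05. Simulated changes were balanced in direction, spread followed the fitted trend, and the control varied like the high-salt pair. The real data have more calls and a trend with expression and length, so these rates need not carry over. Simulated genes were drawn independently, so the list rate cannot test the preset correlation.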

Results

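RNA was sequenced from MDA-MB-231, an established human triple-negative breast cancer cell line, in 1 control sample and in 2 samples grown with 50 mM sodium chloride added to the medium for 24 hours. Total counts were 11953547 in the control, 8836657 in high-salt replicate 1 and 9740650 in high-salt replicate 2. Counts on named genes came to 7959025, 5957956 and 6800559, spread over 8801 genes with a count in the control and 11960 and 13267 in the high-salt libraries. Nothing in the labels says that the 2 high-salt samples came from separate cultures, so p-values measure only the spread between these libraries. The control has no replicate, and it was assumed to vary like the high-salt pair. All genes shared 1 trend of spread, so a gene whose replicates lay far apart was tested with the spread typical of its level.

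The comparison of high salt with control asks which genes differ after 24 hours in medium with added salt. NEAT1 (chromosome 11, 65422798 to 65445540, GRCh38), a long non-coding RNA that builds nuclear paraspeckles, rose from 602 CPM (counts scaled to library size) in the control to 1525 ± 131 (SD, n = 2), a log2 fold change of 1.34 with a standard error of 0.10 (edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p = 6.8e-36). The metallothionein gene MT2A fell from 7888 to 3354 ± 287 (log2 fold change -1.23, SE 0.08) and another, MT1X, from 499 to 167 ± 24.5 (-1.58, SE 0.12). VIM, which encodes the intermediate filament vimentin, fell by 1.00 on the log2 scale (SE 0.08), and CSF2, a cytokine gene, by 1.02 (SE 0.13). These 5 genes passed under each of the 4 scalings that were run. Scaling cannot remove a trend with transcript length, and short coding genes were lower in general. Of coding genes between 312 and 1522 nt, 34 rose and 281 fell. Annotated lengths were 787 nt for CSF2, 2135 nt for VIM and 22743 nt for NEAT1. MT2A and MT1X were singled out after their values were seen.

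Of 7746 genes tested, 2476 passed an adjusted p of 0.05, with 1441 higher and 1035 lower in high salt. The direction followed expression and gene class, which go together here and were not separated. Of the 1441 higher genes 926 were not protein-coding, whereas 932 of the 1035 lower genes were protein-coding. Among all 7746 tested genes 4057 were not protein-coding. Their share was 73.4% under a mean log2 CPM of 1 and 1.82% at 8 or more. Among 713 genes with a mean log2 CPM of at least 8, 33 rose and 525 fell, with a median log2 fold change of -0.49. Among 1653 genes between 1 and 2, 420 rose and 16 fell, with a median of 1.09. In the control 396 of the called genes had no count. The split of 58.2% higher depended on the scaling: it was 46.0% with RLE size factors, 48.0% with upper-quartile factors and 91.5% with library totals alone. Against the TMM scaling, the median of all genes shifted by -0.19, -0.15 and 0.48 on the log2 scale under these 3 choices. Coding genes with 2 or more accessions were called higher more often than those with 1: 34.5% against 14.8% between 3 and 5 log2 CPM, and 22.6% against 8.15% between 5 and 8. SRF, LAMP1 and PSMD2, which rose, have 3 accessions each. Under all 4 scalings 1191 genes were called higher and 233 lower.

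**Figure D1:**
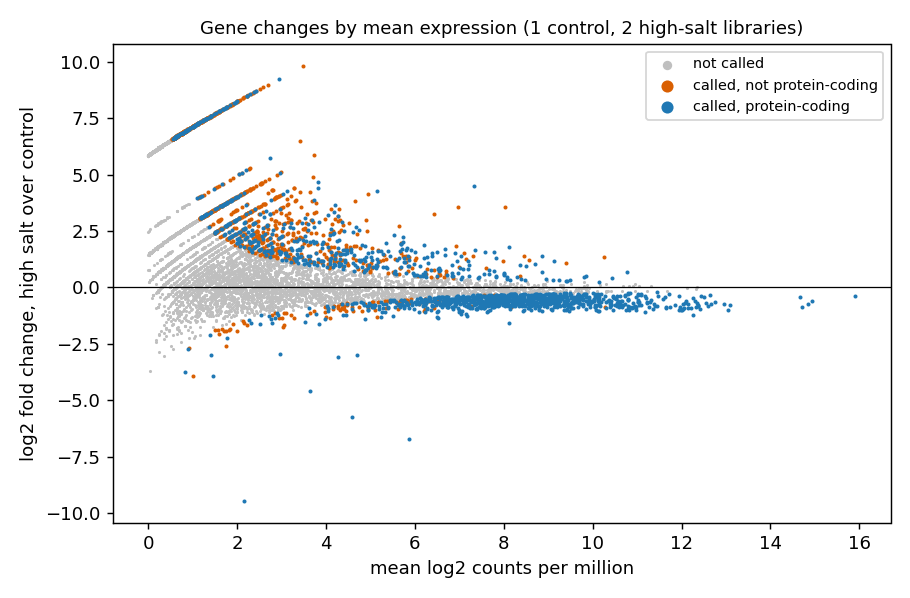
Each point is 1 of the 7746 tested genes, with mean log2 CPM on the horizontal axis and the log2 fold change of 2 high-salt libraries over 1 control on the vertical axis; colour marks called genes by class. Low-abundance called genes lie mostly above 0 and many are not protein-coding, the upper diagonal band holds genes with no count in the control whose fitted values are no measured folds, and abundant called genes lie mostly below 0 under TMM scaling (91.5% of calls were higher with library totals alone).

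The genes with the largest increases had no count in the control. CTNNA2 (chromosome 2, 79185377 to 80648780), which encodes an alpha-catenin of neurons, had 0 counts in the control and 63 and 95 in the high-salt libraries. That is 23.4-fold higher against an assumed control level of 3 counts. LINC01950, MYO5B, SMILR, TSPAN7, MIR4527HG, LINC01501, LINC02107, C7 and ENPP6 followed, from 17.2-fold for LINC01950 to 13.8-fold for ENPP6 against the same level. These folds are not lower limits. The level of 3 counts takes reads as independent, whereas most small counts were even, as when both reads of a pair are counted. A limit that allows for this would be lower, and it would still cover counting error only. The genes with the largest decreases were HSD17B8 (82 counts against 0 and 0), ECH1 (1091 against 12 and 11), TBL3 (442 against 14 and 4), RING1, TTC5, DHRSX, TSPAN16, RNF187, RILP and MINCR. For HSD17B8, ECH1 and RILP 100% of the counts lay on rows of additional sequence copies, and for TBL3 98.9% and DHRSX 99.7%, so these values are uncertain. RNF187, with no counts on such rows, fell by 2.99 on the log2 scale (SE 0.28).

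Among genes of ion transport and cell volume, 2 of 4 measured members rose (2 adjusted over the list alone) and 1 fell (1 adjusted over the list alone). ATP1B1, a beta subunit of the sodium pump, rose by 0.25 on the log2 scale (SE 0.10, adjusted p = 0.032), a call lost with RLE size factors (0.0566, adjusted p = 0.71) and with upper-quartile factors (0.10, adjusted p = 0.54). ATP1B3, another beta subunit, fell by 0.29 (SE 0.10), and with library totals alone its change was 0.19. SCNN1G, a sodium channel subunit, had 0, 6 and 10 counts and did not pass. The list itself did not pass (adjusted p = 0.58), while its median lay at percentile 99.8 among random lists of matched expression.

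The classical osmotic response could be read only in part. NFAT5, the transcription factor of that response, and the osmolyte transporter genes SLC5A3 and SLC6A6 were at 0 counts in every library. SLC6A12 had 0, 4 and 0 counts. For NFAT5 and SLC6A6, with 18 and 9 accessions, zeros do not show absence of expression. Of protein-coding genes with 2 or more accessions 83.0% were at 0 throughout, against 33.9% of those with 1 accession. SLC5A3 has 1 accession, so this reason does not cover it. Its zeros were not explained and do not by themselves show absence. AKR1B1, which makes sorbitol, had 6, 6 and 16 counts (adjusted p = 0.73), and the kinase gene SGK1 had 23, 28 and 50 (adjusted p = 0.47). With so few counts a difference could be missed. AKR1B1 has 3 accessions and SGK1 has 5, so reads shared between transcripts may be missing here too. Of 4 measured members of the osmolyte list, 1 rose and 1 fell, with the same counts adjusted over the list alone. These were HSPA1A (90, 205 and 260 counts) and HSPA1B (472, 206 and 227), near-identical heat shock genes that can share reads, and their opposite changes are uncertain.

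Cytosolic ribosomal protein genes were lower as a group. Of 13 measured members 9 fell and 0 rose, or 10 and 0 adjusted over the list alone (camera, adjusted p = 3.2e-04). With an estimated correlation the camera adjusted p was 0.67. That setting rests on 1 residual degree of freedom and could hardly call any list, here or below. RPL23 went from 6066 to 3017 ± 259 CPM (log2 fold change -1.01, SE 0.08). RPL37A and RPS6 fell by 0.92 and 0.91. The list median was -0.78, and -0.30 with library totals alone, and it lay at percentile 0.12 among lists matched on expression (0.25 with length also matched). Among coding genes with a length the list did not pass (adjusted p = 0.093), nor after a length correction (adjusted p = 0.24, median -0.52). Ribosomal protein genes held 11.5% of named-gene counts in the control (95% Wilson interval 11.4 to 11.5) and 8.27% and 9.06% in the high-salt libraries. Short genes were lower in general: of coding genes between 312 and 1522 nt, 34 rose and 281 fell.

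Genes of the endoplasmic reticulum stress list fell in 6 of 7 measured members and rose in 0, with the same counts adjusted over the list alone (adjusted p = 0.011; adjusted p = 0.67 with an estimated correlation). CALR, a calcium-binding chaperone gene, fell by 0.72 on the log2 scale (SE 0.08), MANF by 0.97 (SE 0.11), HSPA5 by 0.69 and HSP90B1 by 0.68. With library totals alone the list median was -0.20. The call was lost at 1 CPM in all 3 samples (adjusted p = 0.074), among genes of at least 5 log2 CPM (0.12), and among coding genes with a length (0.14, and 0.24 with a length correction). Under TMM it lay at percentile 3.8 among lists matched on expression, and 4.19 with length also matched. In the cytosolic chaperone list 1 member rose and 3 fell of 6, also adjusted over the list alone, and the list did not pass (adjusted p = 0.092; 0.035 with no low-count filter). HSPB1, a small heat shock protein gene, fell by 0.78 (SE 0.09). In the integrated stress response list 2 of 5 members fell, DDIT4 by 0.59 and PPP1R15A by 0.67, and neither passed with library totals alone (-0.11 and -0.19).

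The DNA replication list had 6 of 7 members lower and 0 higher, as it did adjusted over the list alone (adjusted p = 0.024; adjusted p = 0.67 with an estimated correlation). GINS2, part of the replicative helicase, fell by 0.89 (SE 0.16), POLE by 0.78 and E2F1 by 0.49. With library totals alone the list median was 0.00 and the list, POLE, E2F1, CCNB2 and CDC20 did not pass, so these calls rest on the scaling. The list was also lost at 1 CPM in all 3 samples (adjusted p = 0.15), among genes of at least 5 log2 CPM (0.61), and among coding genes with a length (0.27, and 0.24 with a length correction). The list median lay at percentile 23.5 among random lists matched on expression (16.1 with length also matched). In the mitosis list 4 of 7 members fell and 0 rose (4 and 1 adjusted over the list alone), among them CCNB2 by 0.67 and CDC20 by 0.56, and the list did not pass (adjusted p = 0.089; 0.028 with no low-count filter). Of 12 replication-dependent histone genes, 6 were called higher and 0 lower (7 and 0 adjusted over the list alone). H1-4 had 89 counts in the control and 430 and 144 in the high-salt libraries (log2 fold change 1.58, SE 0.28). H3C10 had 14, 87 and 32. The histone list did not pass (camera, adjusted p = 0.97), although its median was 0.60. Camera compares a list with the other tested genes, and the median of tested genes was itself 0.50 under TMM. In most of these histone genes the increase was larger in replicate 1. In replicate 2, under TMM, H1-2, H2AC20, H2BC4, H3C2 and H4C3 lay below the control and the other members above it.

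Among the gene lists, the nuclear non-coding list had the largest median change, 2.13 on the log2 scale. RN7SK, which restrains transcription elongation, had 204 counts in the control and 4017 and 1093 in the high-salt libraries, 375 ± 326 CPM (SD, n = 2) against 32.1 (log2 fold change 3.54, SE 0.15). RMRP, the RNA of a mitochondrial and nucleolar RNA-processing enzyme, had 81, 1304 and 378 counts. Of 4 measured members RN7SK, RMRP and NEAT1 rose and SNHG5 fell by 0.85 (SE 0.09), with 3 and 1 also adjusted over the list alone. The list did not pass (adjusted p = 0.73). Without TMM scaling, structural RNA genes as a class held 65.7 CPM of named-gene counts in the control (95% Wilson interval 60.3 to 71.6), 1372 in replicate 1 (1342 to 1402) and 405 in replicate 2 (390 to 420.2). Intervals cover counting error only.

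**Figure D2:**
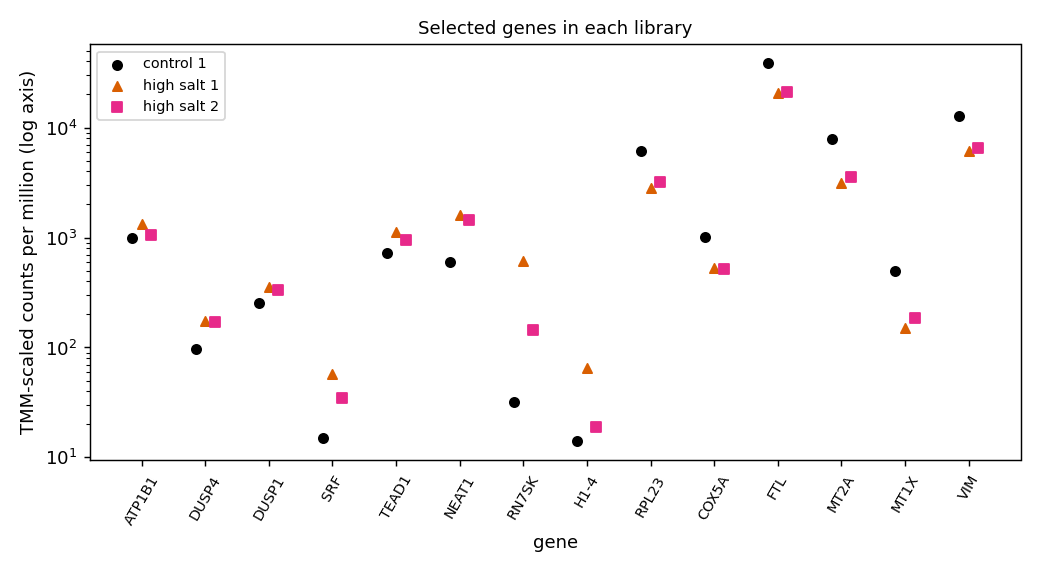
TMM-scaled CPM on a log axis for 14 genes in the control and in both high-salt libraries, 1 symbol per library. SRF and NEAT1 lie above the control in both high-salt libraries, RPL23, MT2A and VIM lie below it in both, and RN7SK and H1-4 differ between the high-salt libraries.

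Of 3 immune lists, antigen presentation and interferon response passed as lower and NF-kB targets did not. The antigen presentation list fell in 4 of 6 measured members and rose in 0, also adjusted over the list alone (adjusted p = 0.024; adjusted p = 0.67 with an estimated correlation). B2M, the invariant chain of class I molecules, fell by 0.98 (SE 0.10), HLA-B by 0.42 and NECTIN2 by 0.54. With library totals alone the list median was 0.00, the list (adjusted p = 0.074) and NECTIN2 did not pass and HLA-B was at 0.0589. The list was also lost at 1 CPM in all 3 samples (adjusted p = 0.15), among genes of at least 5 log2 CPM (0.68), and among coding genes with a length (0.27, and 0.72 with a length correction). The median lay at percentile 37.9 among lists matched on expression and 66.9 with length also matched. HLA-B and HLA-C had over 90% of their counts on rows of additional copies. The interferon list fell in 3 of 4 members (3 adjusted over the list alone; adjusted p = 0.0498; adjusted p = 0.67 with an estimated correlation), BST2 by 0.83, ISG15 by 0.72 and IFITM1 by 0.57. That call was also lost with RLE size factors (adjusted p = 0.058), with library totals alone (0.074, list median -0.16), on ranks (0.058), with a prior count of 0.5 (0.055), at 1 CPM in all 3 samples (0.20), among genes of at least 5 log2 CPM (0.49) and among coding genes with a length (0.29, and 0.61 with a length correction). ISG15 and IFITM1 did not pass with library totals alone, and the list median lay at percentile 14.7, or 56.6 with length also matched. In the NF-kB list 3 of 9 fell, CSF2, NFKBIA and CXCL2, and the list did not pass (adjusted p = 0.20). NFKBIA was at 0.0717 and CXCL2 at 0.0193 with library totals alone.

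Epithelial markers fell in 3 of 5 measured members and rose in 0, also adjusted over the list alone (adjusted p = 0.036; adjusted p = 0.67 with an estimated correlation). KRT19 fell by 0.83 (SE 0.09), CLDN4 by 0.55 and EPCAM by 0.46. With library totals alone the list median was -0.07, the list (adjusted p = 0.074) and CLDN4 did not pass, and EPCAM was at 0.02. The list was also lost at 1 CPM in all 3 samples (adjusted p = 0.15), among genes of at least 5 log2 CPM (0.40), and among coding genes with a length (0.27, and 0.65 with a length correction). The median lay at percentile 14.6 among lists matched on expression and 67.6 with length also matched. Of 6 mesenchymal markers only VIM passed, and the list did not (adjusted p = 0.26). Of 3 actin and SRF genes, SRF, a transcription factor of actin genes, rose by 1.61 (SE 0.27) and ACTB fell by 0.59, which did not pass with library totals alone. TEAD1 rose by 0.51 (SE 0.10) and ARHGEF17 by 0.44, with 2 of 5 members of the YAP list higher, and ARHGEF17 was lost with RLE (0.24, adjusted p = 0.16) and upper-quartile factors (0.29, adjusted p = 0.11). Among immediate early genes DUSP4, DUSP1 and FOS rose, 3 of 11 with 0 lower, and DUSP4 went from 97.3 to 172 ± 1.11 CPM. FOS was lost with RLE size factors (0.0745, adjusted p = 0.63) and upper-quartile factors (0.12, adjusted p = 0.46), and DUSP1 with RLE size factors (0.26, adjusted p = 0.079). ITGB3, an integrin subunit gene, rose by 1.27 (SE 0.40). Of 5 matrix protease genes and inhibitors 3 fell, CTSD by 0.42, MMP14 by 0.44 and TIMP2 by 0.31, and ADAMTS1 rose with 4, 24 and 38 counts. CTSD, MMP14 and TIMP2 were at 0.0632, 0.0439 and 0.17 with library totals alone, and that list did not pass (adjusted p = 0.39). Counts adjusted over the list alone equalled those over all genes for the mesenchymal, actin, YAP, immediate early, integrin and matrix protease lists.

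In the list of nuclear-encoded oxidative phosphorylation genes 7 of 10 fell and 0 rose, also adjusted over the list alone, with ATP5PO at -0.94, COX5A at -0.96 and NDUFA1 at -0.84, and the list did not pass (adjusted p = 0.072). In the glycolysis list PGK1, SLC2A3 and SLC2A1 fell and PGAM1 rose by 0.61, a call lost with RLE (0.42, adjusted p = 0.13) and upper-quartile factors (0.47, adjusted p = 0.087). SLC2A3 was at 0.0451 with library totals alone, and SLC2A1 was then called in the opposite direction, at 0.24 (adjusted p = 0.033). In the hypoxia list CA9, a carbonic anhydrase gene, fell from 675 to 299 and 407 counts and ADM by 0.66 on the log2 scale, and BNIP3L rose from 87 to 315 and 229 counts. Of 9 oxidative stress genes 4 fell, FTL by 0.88, SOD1 by 0.80, HMOX1 by 0.64 and SRXN1 by 0.47 (0.0137 with library totals alone), and 1 rose. In the lysosome list LAMP1, a lysosomal membrane protein gene, rose by 1.93 (SE 0.24) and MAP1LC3B fell by 0.64. In the proteasome list PSMD2 rose by 1.17 and PSMB1 fell by 0.75. Adjusted over the list alone, 2 lysosome genes were higher and 4 lower, 2 proteasome genes higher and 3 lower, and counts of the oxidative phosphorylation, glycolysis, hypoxia and oxidative stress lists were as over all genes. None of these 6 lists passed in the main test. Oxidative phosphorylation was called lower with no low-count filter (adjusted p = 0.021), on genes with 1 accession (0.029) and without additional copies (0.018), and oxidative stress with no low-count filter (0.035) and on genes with 1 accession (0.0499). Of 4 measured p53 targets 2 fell, GDF15 by 0.67 and PLK3 by 0.93, of 6 ribosome biogenesis genes 3 fell, NOP58, NCL and BOP1 (1 higher and 3 lower adjusted over the list alone), and of 7 Notch and Wnt genes 2 fell, HES1 and CCND1, the latter at 0.16 with library totals alone. Of 4 growth arrest genes BTG1 fell by 0.39 (0.0949 with library totals alone), and 2 were lower adjusted over the list alone. Of 4 fatty acid genes 0 passed. The lower calls of PGK1, ADM, HMOX1, MAP1LC3B, GDF15, PLK3, NOP58, NCL, BOP1 and HES1 were lost with library totals alone. In all, 6 of 31 testable lists were lower than the other tested genes and 0 higher. With an estimated correlation 0 passed in either direction. Given 1 residual degree of freedom hardly any list could, so that decides nothing.

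Markers of other cells stayed low, given here as CPM of named-gene counts without TMM scaling. Low values do not show absence of such cells, because 83.0% of protein-coding genes with 2 or more accessions were at 0 throughout. In high-salt replicate 1 a count was present for 3 of 8 luminal, 2 of 8 fibroblast, 2 of 8 leukocyte, 1 of 6 endothelial and 4 of 6 basal markers. Luminal breast markers held 0.251, 2.01 and 1.47 CPM in the control and the high-salt libraries, basal markers 0.377, 3.52 and 2.79, squamous markers 0.251, 2.18 and 1.18, and leukocyte markers 1.76, 6.71 and 2.35. Erythroid markers had 0 counts in the control, which allows up to 0.483 CPM at the upper Wilson bound, and 0.336 and 0.882 in high salt. The endothelial list, from KDR alone, held 5.78, 10.1 and 15.1, and the fibroblast list, from COL1A2 and LUM, 41.0, 69.7 and 67.6. Receptor, keratin-associated and defensin families, which this line is not known to use, held 22.7 CPM over 556 genes in the control and 96.8 and 109 in high salt. Long non-coding RNA genes held 2.53%, 4.43% and 4.43% of named-gene counts.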

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

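The alternatives on transcript rows, accessions, copies, halved counts, expression, length and unnamed rows were chosen after seeing the data. No paired analysis was possible because the labels give the single control no replicate number to share with the high-salt samples. Composition without mitochondrially encoded genes was not run, since none was measured among named rows. The total of 2476 calls became 1386 with at least 1 CPM in all 3 samples, 1570 with DESeq2, 4236 with a fixed coefficient of variation of 0.1, 707 among genes of at least 5 log2 CPM, 1403 among coding genes with a length, 1336 with the length correction and 1413 at 2-fold. The 1441 higher calls became 2502 with library totals, 701 at 1 CPM, 526 with DESeq2 (749 genes had no adjusted p), 2975 and 2458 with fixed coefficients of 0.1 and 0.2, 395 at 5 log2 CPM, 454 and 337 in the length subset without and with correction, and 923 at an adjusted p of 0.01. The 1035 lower calls became 233 with library totals, 685 at 1 CPM, 333 with a fixed coefficient of 0.2, 312 at 5 log2 CPM and 107 at 2-fold. Fewer genes tested or a stricter limit accounts for part of this, and otherwise the cause was not tested. The remaining settings left these counts within 1.5 times. By size alone, with no test, 284 genes were at least 2-fold lower, and 363 to 462 with either high-salt replicate left out (462 without replicate 2). For genes at least 2-fold higher the number was 2781, and 2603 to 2863. Of 155 named genes 83 moved by more than the spread of the high-salt pair without replicate 2, and 1 without replicate 1, and 0 of the called ones changed sign. Under unchanged scaling this rule could not be met, since each of 2 values lies closer to their mean than their SD. The moves therefore come from scaling re-estimated on the remaining 2 libraries and do not measure dependence on a replicate.

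The 6 lower lists became 2 with library totals, 10 with no filter, 1 at 1 CPM and 1 at 5 log2 CPM. They became 0 in the length subset with or without correction, and 0 with an estimated correlation. In that last setting hardly any list could pass, given 1 residual degree of freedom. For the other settings the cause was not tested. With library totals the replication and antigen presentation lists had medians of 0.00 and did not pass (adjusted p = 0.074 for both), and the 2 lists still lower were ribosomal proteins and endoplasmic reticulum stress. Of the named genes 27 lost their call with library totals, 5 with RLE and 4 with upper-quartile factors, 17 at 1 CPM, 6 with no filter, 18 with DESeq2, 9 and 58 with fixed coefficients of 0.1 and 0.2, 4 with robust fitting, 32 at 5 log2 CPM, 10 with the length correction, 3 on genes with 1 accession and 5 on halved counts. With library totals 24 others changed sign: ATP1B3 0.19, BTG1 0.0949, GADD45B 0.44, FEN1 0.0156, PLK1 0.0258, CCNA2 0.19, SLC2A3 0.0451, SLC2A1 0.24, BNIP3 0.43, NFKBIA 0.0717, CXCL2 0.0193, IFIT2 0.35, HLA-B 0.0589, HLA-C 0.15, EPCAM 0.0177, TGFBI 0.25, COL6A1 0.30, CTSD 0.0632, MMP14 0.0439, TIMP2 0.17, ANKRD1 0.30, SRXN1 0.0137, PSMD14 0.0606 and CCND1 0.16. At 5 log2 CPM ATP1B3 was 0.0778, CCNA2 0.0751, SLC2A1 0.12, HLA-C 0.038, TIMP2 0.0551 and CCND1 0.0491, and with the length correction TLN1 was -0.22 and MYH9 -0.29. With unnamed rows included, ribosomal protein shares were 7.63%, 5.58% and 6.33%, structural RNA 0.00438%, 0.0925% and 0.0283%, long non-coding RNA 1.68%, 2.98% and 3.09%, and receptor, keratin-associated and defensin families 0.00151%, 0.00653% and 0.00764%, in the order control, replicate 1, replicate 2.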

Other observations

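All tests in this part were chosen after the result was seen, except the correlation of transcript length with the ratio of the high-salt libraries. Among genes with a mean log2 CPM of at least 5, ranked after seeing the data, UTRN, the gene of the cytoskeletal linker utrophin, rose from 106 to 366 ± 65.2 CPM (log2 fold change 1.79, SE 0.13). CPD rose by 2.24, ARID5B by 2.02, FOXP2 by 1.97, TES by 1.93 and ADGRB3 by 2.30. CAVIN3, a caveolar protein gene, fell by 1.38 (SE 0.17), PDCD5 by 1.32, GAMT, which makes creatine, by 1.17, and NUP37 by 1.11. These values are not corrected for the trend with transcript length described below. Of 67 genes with at least 90% of counts on rows of additional copies and a mean log2 CPM of at least 1, 7 differed at least 4-fold between the high-salt libraries, against 38 of 5626 other genes (Fisher's exact test, two-sided, p = 7.2e-07). GPS2 had 617, 12 and 937 counts and TIMM22 8, 113 and 2.

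Low-abundance and non-coding genes were higher in both high-salt libraries. Lower depth of the control is argued against, since its named-gene total was 1.17 times the larger high-salt total. Long non-coding genes with 1 accession, a mean under 8 CPM and no overlap with another gene were compared. High-salt to control ratios were 4.83 and 7.09 over 100 kb from a coding gene and 1.88 and 1.99 within 20 kb. The quotient was at least 2.56 (bootstrap 95% interval 2.25 to 2.95). It cannot decide alone, since a lower control level far away (311 CPM over 1892 genes against 1335 over 2245) raises such ratios. The excess per gene, given next, was also larger far away in both libraries. For these genes that argues against read-through from neighbouring coding genes as the whole source. Genes that overlap a coding gene were not tested. Uniform genomic DNA may contribute and cannot be told apart: the excess per gene over 100 kb away was 1.20 (95% interval 1.06 to 1.37) and 1.70 (1.51 to 1.91) times that within 20 kb, and the latter was 3.95 and 3.79 times that of receptor, keratin-associated and defensin families, while only 9.89% of low-abundance long non-coding genes have a length to set these against. An effect of salt stays open and untested, with 1 control.

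Short transcripts were lower and long transcripts higher in high salt, with a Spearman correlation across 1321 coding genes of 0.59 between length and the log ratio to control (genes are not independent replicates). Recovery of RNA that depends on length and varies between libraries is a candidate explanation, since the ratio of high-salt replicate 1 to replicate 2 also followed length (0.42), with replicate 1 farther from the control (0.60 against 0.55). For the 5 ribosomal protein genes with annotated lengths of 1526 to 3647 nt, the median was -0.80. It lay at percentile 0.18 among random lists matched on expression and length, which treat genes as independent. That cannot decide against length as the whole cause. Annotated lengths are medians over transcripts, and the RNA present, which could be shorter, was not measured for length. For the 8 of 613 to 1387 nt length as the whole cause stays a candidate explanation, since their median of -0.72 lay at percentile 11.4, with matched lists between -0.81 and -0.15 (middle 95%). An effect of salt on short transcripts stays open and untested.

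Without TMM scaling, structural RNA and replication-dependent histone genes were higher in both high-salt libraries, most in replicate 1. The tested histone genes together held 305, 642 and 390 CPM in the control, replicate 1 and replicate 2. Under TMM the histone list did not pass (camera, adjusted p = 0.97). That compares it with the other tested genes and does not show its members unchanged, since the median of tested genes was 0.50. In replicate 2 the histone list members lay on both sides of the control under TMM. Carry-over of RNA without poly(A) tails that varies between libraries may contribute and cannot be told apart, since the ratio of the replicates is part of the pattern itself and so cannot test it: histone CPM were 1.65 times as high in replicate 1 as in replicate 2 (95% interval 1.57 to 1.73, counting error only), beside 3.39 for structural RNA, 1.13 for NEAT1 and 0.999 for long non-coding RNA. More cells in S phase could not be decided. The DNA replication list had a fitted median of 0.00373 at most over 4 scalings, where the fitted histone median was 1.31. Abundant genes were lower in general, however. Under TMM the replication median lay at percentile 23.5 among random lists matched on expression. The gap to the histone genes therefore cannot be told apart from the trend with expression. An effect of salt on these RNAs stays open and untested.

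The 3 libraries can be split into 1 against 2 in 3 ways, and 1 of the 3 splits, the real one, gave 2476 calls, against 8 as the highest of the others. So few splits cannot give a share under 0.05.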
